A study of Mus musculus with 2 samples.

How the data were processed

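RNA was measured in thioglycollate-elicited peritoneal macrophages of age-matched mouse littermates with and without a functional Pac1 (Dusp2) gene. Per the labels' protocols, 2 ml of 3% thioglycollate was injected into the peritoneum 4 days before the cells were collected with 10 ml of medium, macrophages were purified by adherence for 2 hours, and the preparations were 92 to 95% positive for Mac-1, the integrin encoded by Itgam. The cells received 100 ng/ml LPS for 6 hours. Between 500 and 1000 ng of total RNA was copied to cDNA from a poly(T) primer with a T7 promoter, amplified by a method for small samples, transcribed to biotin-labelled cRNA and hybridised, per the labels' protocols. The number of mice behind each array, and whether RNA of several mice was pooled, are not given in the sources used here.

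The deposited values are 1 intensity per probe set and array, on a linear scale. The authors computed these intensities with MAS5, an algorithm that combines the perfect-match and mismatch probes of a probe set into a signal, per the submitters' processing notes, which name no version or settings. The 2% trimmed means of the 2 arrays were equal in the deposited values, which shows that both had been scaled to the same level. No value was below 0, and detection calls were not used here, so a floor on the signal took their place. Such 3′-primed amplification weights the 3′ ends of transcripts, and signals of different probe sets are not comparable with each other, so values were compared only between arrays for the same probe set. The number of arrays, 1 per genotype, limits the precision.

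Probe sets were named through an annotation table of the array's platform. Of the 12654 probe sets, 10298 had 1 gene symbol, 363 had several and 1993 were not in the table. Of the named ones, 10279 had an Entrez identifier in a reference gene table (assembly GRCm38.p6), which changed 0 symbols, and the table's coordinates were not used. The 66 control probe sets, and those with several symbols or none, stayed out of the gene table, which held 8220 genes. For the 1609 genes with several probe sets, the one with the highest mean signal was used. This array generation held some probe sets designed against the wrong strand, and these were not identified here.

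Each array was scaled to the same 2% trimmed mean, which left them nearly as they were (factors of 1 after rounding, against 5115 eligible genes and 56 lower ones without it). Signals were then raised to a floor, the median of all signals of both arrays (36.4), and the log2 ratio of knockout over wild type was taken. A gene was eligible when at least 1 of its signals was above the floor, which held for 5119 genes, 4400 of them above it on both arrays. For a gene with 1 signal below the floor, the fold is the brighter signal over the floor and is written as "at least". Genes were counted when 2-fold or more apart. No test, p-value or standard error across genes was computed for the genotypes, because genes are not replicates. As a description of how unusual a ratio was, the 200 eligible genes nearest in mean signal were searched for differences as large. For genes named because of their extreme ratios, a low count follows from that choice and is no separate evidence. Over probe sets above the floor on both arrays, log2 signals correlated between the arrays with r = 0.978 across probe sets, which are not independent replicates.

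Gene lists covered cytokines and growth factors, chemokines, chemoattractant receptors, interferon-stimulated genes, prostanoids and leukotrienes, nitric oxide with arginine and the oxidative burst, the Toll-like receptor and NF-kB pathway, dual-specificity phosphatases, MAP kinase components, AP-1, ETS and immediate early genes, alternative activation, MHC class II and costimulation, proteases and matrix, complement and acute phase, adhesion, survival and death, heat shock and unfolded protein response, cholesterol and lipids, glycolysis and hypoxia, oxidative phosphorylation, cell cycle, housekeeping and ribosomal proteins. Further lists held markers of macrophages, neutrophils, eosinophils, mast cells and basophils, B cells, T and NK cells, dendritic cells, mesothelial and stromal cells, endothelial cells, erythroid cells with platelets, and genes of X-inactivation and the Y chromosome. There were 34 lists in all. For the 30 with at least 5 eligible members, the median log2 ratio was placed among the medians of 10000 random lists of the same size, matched on mean signal in 20 bins, and described as outside when it lay beyond their central 95%. These percentiles describe the 2 arrays and say nothing of other mice.

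The lists, the scaling, the floor, the size rule, the alternatives and the rule for named genes were fixed before the data were examined. The rule named Dusp2, the 12 genes with the highest and the 12 with the lowest ratio among those with both signals above the floor and at least 1 above 2 times the floor, and up to 5 per direction with 1 signal below the floor and the other at least 4 times the floor. It also named the members of each list that were 2-fold apart (or the 3 highest and 3 lowest if over 6), otherwise up to 2 members with the largest ratios, and always Tnf, Il1b, Il6, Il10, Il12b, Nos2, Ptgs2, Ccl2, Cxcl2 and Cxcl10. Further list members are named as examples and were chosen after their values were seen.

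The alternatives were the deposited values without further scaling, scaling to the same median, quantile normalization, loess of the log2 ratio on mean log2 signal (span 0.3), a floor at the 25th or 75th percentile of the signals, no floor, the mean over a gene's probe sets, leaving out probe sets whose suffix marks possible cross-hybridisation, and size rules of 1.5-fold and 3-fold. The steps were tested on simulated data, in which 8220 genes were given the observed signals and shuffled ratios. Genes were altered only among eligible ones with a wild-type signal above the median of all genes, so their recovery does not describe dimmer genes. Of 100 genes made 4-fold different, 87 were counted at 2-fold, as were 84 of 100 made 2.5-fold different and 124 of 4940 unchanged genes (2.51%). The unchanged genes carried the observed spread of ratios, so this last share repeats the observed one and is no error rate. The interferon-stimulated list, with 30 of 33 members over 4 times the floor in the observed data, was lowered by 0.5. It was recovered with a median of −0.41, and 5 of 100 unchanged lists lay outside the central 95%. Those 100 lists were drawn at random from the shuffled data, so their share follows from the construction and is no error rate for real lists. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and figures were drawn with matplotlib 3.10.9.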

Results

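Gene expression was measured in mouse macrophages that lacked PAC1 and in macrophages of wild-type littermates after stimulation with lipopolysaccharide (LPS), the cell-wall component of Gram-negative bacteria that triggers Toll-like receptor 4. PAC1 is the protein of the gene Dusp2, a dual-specificity phosphatase that acts on MAP kinases in the nucleus. The cells were recruited to the peritoneum with thioglycollate, a sterile irritant, purified by adherence and exposed to 100 ng/ml LPS for 6 hours. The comparison asked which inflammatory genes differ with the genotype, and per the labels the 6 hours were chosen for inflammatory gene expression. The data comprised 2 Affymetrix arrays, 1 from Pac1 knockout cells and 1 from wild-type cells, each with signals for 12654 probe sets. The signals were MAS5 intensities in arbitrary units, with medians of 38 on the knockout array and 35 on the wild-type array and equal trimmed means. Unstimulated cells were not analysed here, so values describe the level after LPS and not its induction. With 1 array per genotype no difference has a replicate check, no test of the genotypes was possible, and sizes are given without p-values.

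The Dusp2 signal was 76.8 on the knockout array and 333.0 on the wild-type array, 23.1% of the wild-type level (log2 ratio −2.12, from the single Dusp2 probe set). It was the lowest ratio among the genes measured above the floor on both arrays. None of the 200 genes nearest to it in mean signal had as large a difference (0 of 200). The knockout signal was still above the floor of 36.4, and whether the probes lie in the deleted part of the gene is not given in the sources used here, so the value is only a partial check of the labels.

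After LPS, the transcript of the inflammatory cytokine interleukin-6 was lower on the Pac1 knockout array than on the wild-type array. Il6 was 3.95-fold lower, at 366 against 1448, and was the only 2-fold lower gene among 20 cytokine genes. Procr, which encodes the endothelial protein C receptor, was 3.21-fold lower, and Cxcl5, a neutrophil-attracting chemokine, was 2.76-fold lower. In the other direction, Arg1 (arginase) was 2.31-fold higher and Gatm, the enzyme of the first step of creatine synthesis from arginine, was 3.07-fold higher. Tnf, Il1b and Ccl2, other mediators of activated macrophages, were within 1.5-fold of the wild-type level.

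Across the 5119 eligible genes, those above the floor on at least 1 array, 63 were 2-fold or more higher in the knockout and 55 were 2-fold or more lower, together 2.31% of the genes, while 87.9% lay under 1.5-fold apart. When the arrays were scaled to the same median instead of the same trimmed mean, the split was 43 higher and 86 lower, since that scaling moved the median log2 ratio of all eligible genes by −0.11, from 0.02 to −0.10. Most of the 2-fold genes were dim, with a median of 100.0 for the brighter of the 2 signals against 139.9 for all eligible genes. Only 2 of the higher genes (Gatm and Arg1) and 7 of the lower genes had a signal above 300 on either array, and those 7 were Dusp2, Il6, Procr, Chil3, Fmr1, Stag2 and St8sia4. Stag2 (300 in the knockout against 651) and St8sia4 (359 against 768) were named after their values were seen.

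**Figure D1:**
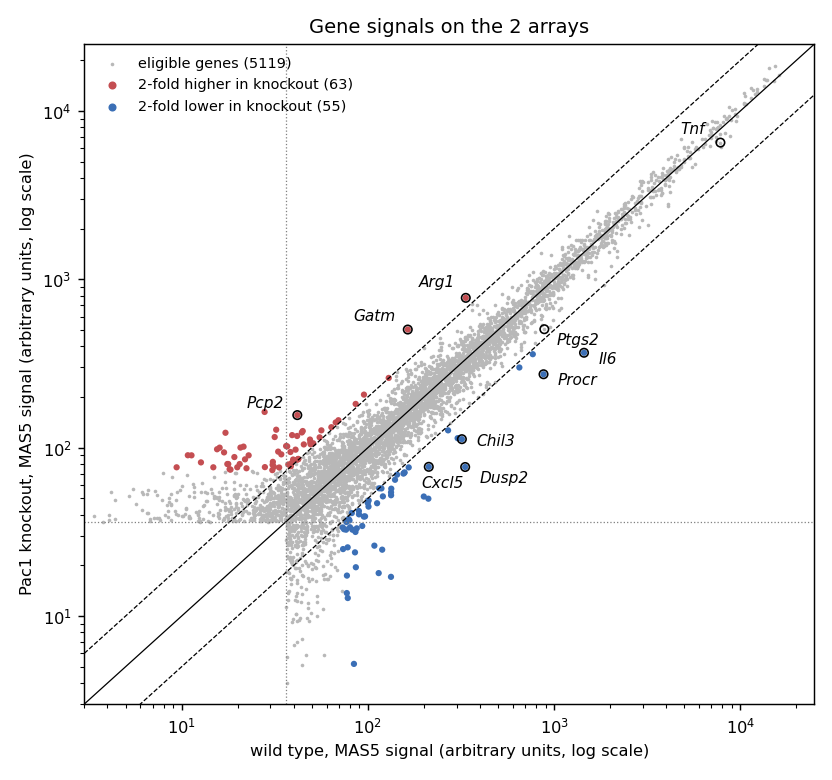
Signals of the 5119 eligible genes on the wild-type array (horizontal) and the Pac1 knockout array (vertical), in arbitrary MAS5 units on log axes, with dashed lines at 2-fold and dotted lines at the floor of 36.4. Points show signals without the floor and are coloured by the ratio with it, so some grey points lie beyond the dashed lines. The 63 genes in red and 55 in blue lie mostly at low signals, and Il6, Procr, Gatm and Arg1 stand apart at higher signals.

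The 12 genes with the lowest ratios were, after Dusp2, Sh3bp1, Il6, Slc30a4, Procr, Chil3, Cxcl5, Fmr1, Acta2, Osbpl5, Col4a1 and Plk1. Sh3bp1 was at 49.8 against 211 (log2 ratio −2.09). The zinc transporter gene Slc30a4 was at 51.3 against 200 (−1.96), and its other probe set was below the floor on both arrays. Procr was at 273 against 877 (−1.68), and Chil3, which encodes the chitinase-like protein Ym1, was at 112 against 320 (−1.51). Cxcl5 was at 77.0 against 212 (−1.46) and Fmr1, the gene of an RNA-binding protein of translation control, at 114 against 303 (−1.41). For Sh3bp1, Il6, Procr, Chil3 and Cxcl5, 0 of the 200 genes nearest in signal differed as much. Of these only Il6 was named before its value was seen, and for the others a low count follows from their choice by ratio. The smooth-muscle actin gene Acta2 (−1.35), the collagen gene Col4a1 (−1.29), Osbpl5 (−1.30) and the mitotic kinase gene Plk1 (−1.29) were dimmer, and the brightest of their signals was 133. The suffix of the Plk1 probe set marks possible cross-hybridisation, its other probe set was below the floor on both arrays, and without such probe sets the gene had no value.

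The 12 genes with the highest ratios were Pcp2, Gatm, Bdkrb1, Tcta, Gng3, Apbb1, Grb7, Uchl1, Vps72, Arg1, Dtx1 and Commd5. Gatm was at 503 against 164 (log2 ratio 1.62) and Arg1 at 776 against 336 (1.21). As large a difference occurred in 0 and 1 of their 200 nearest genes, but both were chosen by their ratios. The other 10 were dimmer, and the brightest of them, Pcp2, was at 156 against 41.8 (1.90), from its only probe set, whose suffix marks possible cross-hybridisation. The bradykinin receptor gene Bdkrb1 was at 119 against 39.2 (1.60). Tcta, Gng3, Apbb1 and Grb7 had ratios between 1.47 and 1.49, and Uchl1, Vps72, Dtx1 and Commd5 had ratios between 1.19 and 1.30. Cplx1, a gene of the complexin family, had 163 in the knockout and a wild-type signal below the floor, at least 4.48-fold higher.

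Of the 20 eligible members of the list of inflammatory cytokines, 13 had ratios below 0 and 7 above, with 1 (Il6) 2-fold lower and 0 2-fold higher. Their median log2 ratio was −0.16, at percentile 0.69 among 10000 random lists of the same size and signal, whose central 95% ran from −0.13 to 0.16. After Il6, the lowest were Il12a at 160 against 293 (−0.87), Il12b at 44.3 against 74.8 (−0.76), Ltb (−0.75) and the granulocyte growth factor Csf3 at 187 against 301 (−0.69). Il12b and Ltb were dim, and 44 and 65 of their 200 nearest genes differed as much, against 3 for Il12a and 10 for Csf3. Il1b was at 6147 against 7831 (−0.35), Tnf at 6490 against 7817 (−0.27) and the receptor antagonist gene Il1rn at 13564 against 12268 (0.14). The anti-inflammatory Il10 was at 170 against 192 (−0.17), and 107 of its 200 nearest genes differed as much. Lta, at 91.8 against 50.2 (0.87), had the highest ratio of the list.

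**Figure D2:**
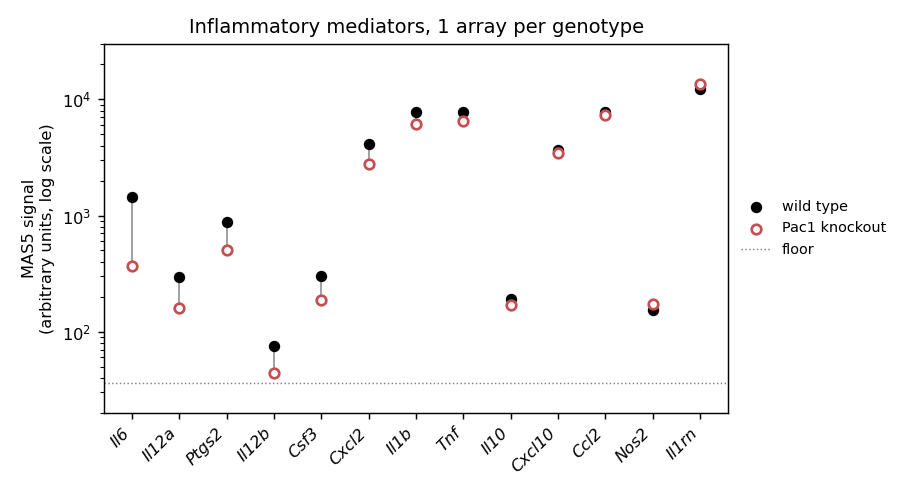
MAS5 signals (arbitrary units, log axis) of 13 inflammatory mediator genes on the wild-type array (filled) and the Pac1 knockout array (open), with the floor dotted. The gap is widest for Il6 (1448 against 366), and Tnf, Ccl2 and Cxcl10 lie close together.

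Among chemokines, 12 of 18 members were below 0, 1 (Cxcl5) 2-fold lower and 1 (Cxcl13) 2-fold higher. The list's median was −0.11, at percentile 1.39 of its random lists (central range −0.09 to 0.16), but it lay inside that range with a floor at the 25th percentile of the signals (percentile 3.18) or with no floor (5.55). The neutrophil attractants Cxcl2 (2796 against 4105, −0.55) and Cxcl1 (2263 against 2948, −0.38) were lower, and 3 and 8 of their 200 nearest genes differed as much. Ccl2 was at 7271 against 7730 (−0.09) and Cxcl10 at 3423 against 3681 (−0.10). Ccl6 was higher, at 446 against 243 (0.87), and the B cell attractant Cxcl13 was at least 3.51-fold higher, from 128 against a wild-type signal below the floor.

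Among genes of the prostanoid and leukotriene pathway, Ptgs2, the inducible cyclooxygenase, was at 506 against 886 (log2 ratio −0.81), a difference matched by 2 of its 200 nearest genes. The dim receptor gene Tbxa2r was at 40.3 against 78.1 (−0.95), and 31 of its 200 nearest genes differed as much. The list as a whole had 0 of 13 members 2-fold apart and a median of −0.08, at percentile 24.2. With a floor at the 75th percentile of the signals, which left 8 eligible members, its median was 0.04 (percentile 70.6). Of 8 chemokine and chemoattractant receptor genes, 0 were 2-fold apart and the median was 0.09 (percentile 81.5), with C3ar1 at 702 against 483 (0.54) and Ltb4r1 lower by at least 1.90-fold.

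The list of AP-1, ETS and immediate early genes, mostly transcription factors, had 16 of 20 members below 0 and 0 of them 2-fold apart. It includes Mcl1 (1295 against 1402, −0.11), a survival protein gene that the survival list also holds. Their median was −0.15, at percentile 0.94 of random lists (central range −0.12 to 0.15). The lowest were Atf2 (182 against 247, −0.44) and Junb (882 against 1115, −0.34), while Atf3 was higher (6039 against 4995, 0.27). The other dual-specificity phosphatases were nearer to the wild-type level than Dusp2. Dusp1, an induced MAP kinase phosphatase, was at 2238 against 1621 (0.46), Dusp6 was at 110 against 141 (−0.35), and the 8 members had a median of −0.06 (percentile 31.8), with 1 (Dusp2) 2-fold lower. Of 19 MAP kinase pathway genes 0 were 2-fold apart, with a median of −0.07 (percentile 19.5) and a mean of 0.04. Their largest ratios belonged to Map2k4, the kinase upstream of JNK (295 against 182, 0.69), and Mknk2 (70.0 against 49.3, 0.51, but −0.15 as the mean over its 2 probe sets).

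The interferon arm of the LPS response was close to equal on the arrays. The 33 interferon-stimulated genes, with 17 above and 16 below 0 and 0 of them 2-fold apart, had a median of 0.01 (percentile 31.6), which was −0.11 with arrays scaled to the same median and −0.03 after quantile normalization or loess. Isg15 was at 11076 against 10685 and Ifit1 at 9320 against 8728, and the widest ratios were those of the dim Oas1g (0.82) and of Iigp1 (218 against 310, −0.51). Genes of the Toll-like receptor and NF-kB pathway and its feedback had 12 of 27 members above 0, 0 of them 2-fold apart, and a percentile of 45.1. Within this list Ier3 was lower (533 against 860, −0.69) and Ikbkb had the highest ratio (0.42).

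**Figure D3:**
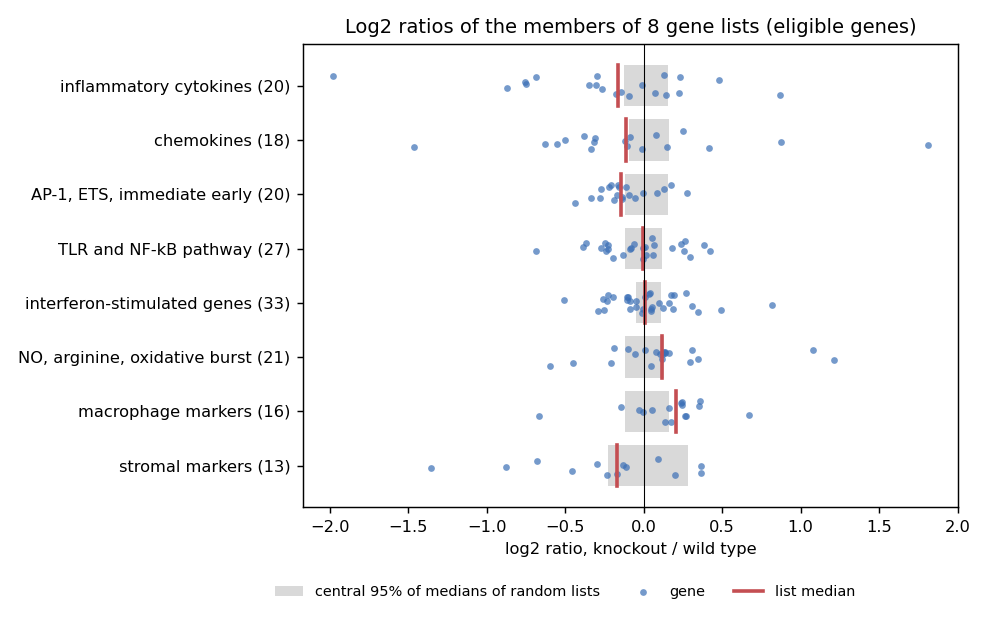
Log2 ratios (knockout over wild type, 1 array each) of the eligible members of 8 gene lists, with list medians in red and the central 95% of medians of random lists matched in size and signal in grey. Medians of cytokines (−0.16), chemokines (−0.11) and AP-1, ETS and immediate early genes (−0.15) lie below the grey range and that of macrophage markers (0.21) above it.

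Genes of nitric oxide, arginine and oxidative burst had 15 of 21 members above 0, 2 of them 2-fold higher (Arg1 and the catalase gene Cat, the latter by at least 2.12-fold, but with a log2 ratio of 0.82 as the mean over its 2 probe sets) and 0 2-fold lower. The median was 0.12, at percentile 94.7, and just below 0 with arrays scaled to the same median. Nos2, the inducible nitric oxide synthase that competes with arginase for arginine, was at 172 against 154 (0.16), and 112 of its 200 nearest genes differed as much. Markers of alternative activation went both ways, with Arg1 2-fold higher, Chil3 2-fold lower and the scavenger receptor gene Msr1 at 1366 against 2171 (−0.67). The 11 members had a median of −0.10 (percentile 17.8).

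General macrophage and monocyte markers were slightly higher in the knockout, with 12 of 16 above 0 and 0 of them 2-fold apart. Their median of 0.21 lay at percentile 99.6 of random lists (central range −0.12 to 0.16), and with arrays scaled to the same median it was 0.09. Csf1r, the receptor for macrophage colony-stimulating factor, was at 1090 against 852 (0.35), the Fc receptor gene Fcgr1 at 3771 against 2939 (0.36) and Cd68 at 4582 against 3821 (0.26). Msr1 went against the group and the dim Fcgr3 had the highest ratio (at least 1.59-fold).

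Antigen presentation and costimulation genes had a median of 0.08 over 12 members (percentile 79.7) and a mean of −0.07. The costimulatory ligand gene Cd86 was lower (241 against 447, −0.89), and 2 of its 200 nearest genes differed as much. Ciita, the activator of MHC class II genes, was at least 1.73-fold lower. Complement and acute phase genes had 11 of 15 above 0 and a median of 0.11 (percentile 93.5), with C3ar1 highest and C2 lowest (50.7 against 91.9, −0.86). Proteases, inhibitors and matrix genes had a median of 0.11 over 23 members (percentile 90.8) and a mean of −0.02, with the proteoglycan gene Vcan (378 against 665, −0.82) and Mmp9 (51.3 against 82.6, −0.69) lowest. Adhesion molecules had a median of 0.05 over 19 members (percentile 69.0), led by Cd44 (0.41) and Icam1 (0.30). In the main processing none of these 4 groups had a member 2-fold apart. Without cross-hybridising probe sets, 1 of 15 complement and acute phase genes was 2-fold lower. With arrays scaled to the same median, 1 of 12 antigen presentation and costimulation genes was 2-fold lower, and the positive medians of all 4 groups became negative.

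Cholesterol and lipid handling genes had 16 of 28 below 0 and a median of −0.11 (percentile 3.40), with the nuclear receptor gene Rxra (69.4 against 131, −0.92) and the sterol synthesis gene Cyp51 (81.3 against 139, −0.77) lowest. Their median lay outside the random range with quantile normalization (percentile 2.18), with loess (1.71) and with a floor at the 25th percentile of the signals (0.935). Survival and death genes had a median of 0.02 over 21 members (percentile 61.2) and a mean of −0.01, and the stress-induced growth arrest gene Gadd45a was at least 3.28-fold lower (119 in the wild type, below the floor in the knockout). Heat shock and unfolded protein response genes, 26 in number, had 13 above and 13 below 0 (percentile 47.8), with Dnajb9 lowest (−0.82) and Herpud1 highest (at least 1.77-fold). Glycolysis and hypoxia genes had a median of −0.01 over 17 members (percentile 32.4) and a mean of 0.02, with Pfkfb3 at −0.54 and Pfkp at 0.44. Oxidative phosphorylation genes had a median of 0.02 over 32 members (percentile 56.3), with Atp5c1 at 0.53 and Uqcrb at −0.46. Cell cycle genes had 13 above and 14 below 0 among 27 (percentile 30.8), with Plk1 2-fold lower and Aurkb at least 2.69-fold higher. Ribosomal protein genes had a median of 0.02 over 25 members (percentile 30.8), between Rps29 (−0.51) and Rpl41 (0.34). Apart from Gadd45a, Plk1 and Aurkb, 0 members of these 7 groups were 2-fold apart.

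Markers of other cells that a peritoneal lavage could hold were mostly dim. Stromal and mesothelial markers had 9 of 13 below 0 and a median of −0.17 (percentile 6.81), with Acta2 2-fold lower, and dendritic cell markers had a median of −0.22 over 7 members (percentile 3.98), with Batf3 at −0.39 and Flt3 at −0.34. The dendritic cell median depended on the processing. It was 0.03 (percentile 55.7) with a floor at the 25th percentile of the signals and −0.09 (percentile 21.0) without cross-hybridising probe sets. B cell markers had 6 of 8 below 0 and a median of −0.21 (percentile 8.58), although Cd79a was at least 2.75-fold higher. Their median was 0.07 (percentile 53.4) with no floor and −0.08 (percentile 24.2) as the mean over a gene's probe sets. Neutrophil markers had a median of −0.07 over 7 members (percentile 20.4), with Csf3r at −0.37 and Camp at 0.47. Mast cell and basophil markers had a median of 0.13 over 5 members (percentile 74.8), with Tpsb2 at 0.73 and Hdc at −0.45. T and NK cell markers had a median of 0.22 over 5 members (percentile 72.8), with Cd4 at least 2.05-fold lower. Fewer than 5 members were eligible for eosinophils (2, with Prg2 at least 2.75-fold higher), endothelial cells (2, with Vwf at −0.40 and Eng at 0.01) and erythroid cells and platelets (3, with Hba-a1 at least 2.14-fold lower), and 0 for genes of X-inactivation and the Y chromosome.

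Signs of RNA quality were alike on the arrays. The ratio of the 3′ to the 5′ control signal was 2.42 in the knockout and 2.54 in the wild type for actin, and 1.62 and 1.81 for Gapdh. Housekeeping genes had 0 of 14 members 2-fold apart, a median of 0.04 (percentile 55.4) and a mean of −0.02, and the median was −0.08 with arrays scaled to the same median, −0.04 after quantile normalization and −0.01 after loess. They were not uniform, since Ywhaz was at 2099 against 3184 (−0.60) and Actb at 2739 against 4073 (−0.57, from a probe set whose suffix marks possible cross-hybridisation), whereas the array's own actin control probe sets were higher in the knockout, by 0.30 at the 3′ end, 0.46 in the middle and 0.37 at the 5′ end.

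Of the 30 lists set against random lists, 4 lay outside the central 95%, where 1.5 would be expected for lists of randomly drawn genes. Genes of a real list can vary together, and some lists share genes, so 4 against 1.5 does not measure an excess over chance. With arrays scaled to the same median, 12 of the 15 lists with a positive median had a negative one, the exceptions being macrophage and monocyte, mast cell and basophil, and T and NK cell markers. Between 2 probe sets of the same gene the log2 ratios differed with an SD of 0.52 over 569 genes, so that ratios of single dim genes well under 2-fold were within this scatter. It was measured within 1 pair of arrays and holds no variation between repeated arrays, cultures or mice.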

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

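All tests in this part were chosen after the results were seen. Signals outside the gene table were higher on the knockout array in 9 of 9 antisense probe sets of the bacterial spike genes, which should detect no mouse transcript and lay outside the comparison. Without the floor, their median log2 ratio was 1.27 and their median signals were 57.6 in the knockout and 24.4 in the wild type. Of the 9 wild-type signals 5 were below the floor, and with the floor the median was 0.66. The 19 sense probe sets of unspiked bacterial and yeast genes, which should detect no mouse transcript either, were below the floor on both arrays, and without it 10 of 19 were higher, with median signals of 5.1 in the knockout and 9.3 in the wild type. The sense probe sets of the spike genes BioC, BioDn and CreX differed by a median of 0.11 (6 of 6 higher). The spike gene BioB, included among the antisense probe sets, was left out of this sense set. Its sense probe sets were below the floor on both arrays, with log2 ratios of −0.07, −0.40 and 0.87 without the floor.

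Dim genes made up most of the 2-fold differences, and 2 technical explanations were weighed. Among the 1706 dimmest eligible genes 4.81% were 2-fold apart, against 0.352% of the 1706 brightest. These shares describe the pattern itself and cannot tell scatter of dim signals from another source. Between 2 probe sets of a gene, log2 ratios differed with an SD of 0.34 where both had a mean signal of 150 or more, and 0.57 in the other pairs. Scatter was thus larger for dim signals, but how many of the 2-fold differences it accounts for is not known. In signals without the floor, a background added to every probe set of the knockout array, of the 34.2 units by which the antisense probe sets differed, would need a median log2 ratio of 2.56 in the dimmest 40% of probe sets, and the tables argue against it, since that median was 0.17. Which dim genes differ with the genotype stays open, because each was measured on 1 array per group.

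Outside the gene table, 10 probe sets with no or several gene symbols were 2-fold or more higher in the knockout and 12 were lower, among 940 above the floor. Among the 12 lower ones, the widest ratio was that of a probe set with no gene symbol, at 38.5 against 292 (log2 ratio −2.92, 7.59-fold), wider than that of Dusp2. The 12 also included a probe set shared by immunoglobulin kappa genes, at 288 against 900 (−1.64), and a probe set shared by beta-globin genes, at 66.2 against 165 (−1.32). Among the 10 higher ones, a probe set of the Rpl29 family was at least 3.57-fold higher. The suffixes of this probe set, of the beta-globin one and of the one with the widest ratio mark possible cross-hybridisation.

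The immunoglobulin signal could come from fewer B cells in the knockout preparation, a candidate source that adherence and the Mac-1 check should have limited. Ighm was also lower (123 against 230, −0.90), as were Igkv6-23 (46.8 against 112, −1.26) and Ms4a1 (−0.74). Cd79b lay closer to the wild-type level (−0.15), but Cd79a was higher by at least 2.75-fold and Cd22 was at 197 against 177 (0.15). The Ighm value comes from 1 of its 16 probe sets, whose suffix marks possible cross-hybridisation, as does that of the Igkv6-23 probe set. The 8 B cell markers, 0 of them in another list, had a median of −0.21, inside the range of random lists (−0.33 to 0.37), and with only 2 of them over 4 times the floor they decide neither for nor against that source. A difference that goes with the genotype was not tested and stays open.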

How the results depend on the processing

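In the 686 values that could be computed for 81 named genes under 9 alternatives of scaling, floor and probe sets, the direction was kept apart from Eng near 0 and Mknk2 (−0.15 as the mean over its probe sets). Some dim genes had no value at the 75th percentile floor, and others, among them Plk1 and Pcp2, had none without cross-hybridising probe sets. Of the values 0 of those 2-fold apart were reversed and 28 moved by more than the scatter of a probe set's log2 ratio (0.36). Of 220 values for the 25 lists not singled out, 31 moved by more than the SD of random-list medians. Scaling to the same median gave 86 lower genes, including all 55, and 43 higher, and medians of −0.28 for cytokines, −0.22 for chemokines, −0.11 for interferon-stimulated genes, −0.26 for AP-1, ETS and immediate early genes and 0.089 for macrophage markers, because it lowers the ratios of all genes. The interferon-stimulated median was −0.031 after quantile normalization and −0.034 after loess. A lower floor admits dimmer signals, with 476 higher and 344 lower genes at the 25th percentile and 876 and 670 with no floor, which included all 63 and 55. At the 75th percentile 2 higher and 8 lower genes remained of those, and Dusp2 was at −1.36 because its knockout signal lay below that floor. A 1.5-fold rule counted 326 higher and 293 lower genes, and a 3-fold rule 7 and 8. Cytokines, AP-1, ETS and immediate early genes and macrophage markers lay outside the random range in all 9 alternatives, and without Il6, an alternative chosen after seeing the data, the cytokine median was −0.15 (percentile 1.71). The number of arrays and, for dim genes, signal over background limit these results. No paired analysis was possible because each genotype had 1 array, and no array could be left out.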

Other observations

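All tests in this part were chosen after the results were seen, as were the genes Ckb, Slc6a8, Slc7a2, Arg2, Ass1, Oat, Gamt, Odc1, Srm, Sat1, C1qa, C1qb and C1qc. Genes of arginine use went in different directions. Gatm and Arg1 were the only genes above 300 that were 2-fold higher in the knockout, and brain-type creatine kinase, Ckb, was also higher (2536 against 1697, log2 ratio 0.58), whereas the creatine transporter gene Slc6a8 was at 286 against 336 (−0.23). The arginine transporter gene Slc7a2 was lower (1445 against 1972, −0.45), and Nos2 (0.16), Arg2 (0.05), Ass1 (−0.06), Oat (−0.22) and the creatine enzyme Gamt (−0.16) lay closer to 0. Of polyamine genes, Odc1 had a ratio of at least 0.54 (wild-type signal below the floor), Srm a ratio of −0.31 and Sat1 a ratio of 0.12.

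Complement component C1q, a macrophage product, had C1qb (1709 against 1309, 0.39) and C1qc (1599 against 1233, 0.37) higher in the knockout and C1qa nearly equal (731 against 726, 0.01). These ratios were under 1.5-fold.

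Il6 and the cytokine list were lower in the knockout, and 3 explanations other than a direct effect of the genotype were weighed. A weaker LPS response that lowered all induced genes as far as Il6 is argued against by the interferon-stimulated genes, 0 of them in another list. Their median was 0.010 (SD 0.25 between members) against −1.98 for Il6. Il6 had the lowest ratio of its list, so a weaker response that lowers genes unequally, or spares the interferon arm, stays open. For the cytokine list a weaker response of all induced genes stays open too. The gap of 0.17 between the medians of the lists lay at percentile 97.2 of gaps between 10000 pairs of random lists. That is just inside their central 95% (−0.15 to 0.18). Fewer stromal cells, which also make interleukin-6, stay open as a source of the Il6 difference. The stromal markers had a median of −0.17 (SD 0.50, 0 of 13 markers in another list), with 9 of 13 below 0. Only 6 of the 13 were over 4 times the floor, and the floor limits how far the dimmer ones could fall. Acta2 (52.2 against 133, −1.35), Pdgfra (236 against 432, −0.88) and Sparc (−0.68) were lower. A difference between single cultures or arrays and an effect of the genotype cannot be told apart, because 4 lists outside their random range come from 1 array per group. A lower Il6 transcript in LPS-stimulated Pac1 knockout macrophages may therefore be a genotype effect only as a hypothesis that repeated cultures would have to test.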
